A study of Homo sapiens with 9 samples.

How the data were processed

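RNA from cultured human lung mesenchymal progenitor cells (MPC) was measured on 9 single-colour Affymetrix gene expression arrays, 5 of control lines and 4 of lines from lungs with idiopathic pulmonary fibrosis (IPF). Per the labels, each line came from a different patient, the cells were grown from explanted lung and harvested before confluence, and the RNA was labelled with biotin. Groups were taken from the disease state in the labels, and replicate numbers only name the lines and pair none of them.

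The authors deposited 1 table of log2 values with 33297 probe sets for each of the 9 arrays. The R package oligo is named per the submitters' processing notes. Its version, the background correction, the normalization and the genome build are not given in the sources used here. The values ran from 1.04 to 13.43 on the log2 scale and were used as deposited, with no filter on dim probe sets. Detection calls were not analysed here, so no level was set against background, and the number of arrays limits the precision of every value. For arrays no depth applies.

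Probe sets were named through the platform annotation supplied with the data. It gave 1 gene for 19460 probe sets, several for 1754 and none for the other 12083, which are unnamed here. Entrez identifiers of 19429 of the named probe sets matched a RefSeq gene table (assembly GRCh38.p14, used for names and gene types), and 0 symbols needed updating. Probe sets with several genes were not named. Genes on the Y chromosome, XIST and TSIX, 23 genes in all, were left out of tests and texts. Each gene was represented by its probe set with the highest mean over the 9 arrays, which mattered for the 768 genes with more than 1, and 18394 genes were tested. Levels of different probe sets were not compared with each other, except that ABCG2 was set against the percentiles of its arrays.

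The values showed that the arrays fall into 2 sets. Arrays were put in the same set where they shared exact values, so arrays of different sets share 0 by definition. Any 2 arrays within a set shared at least 140. The first set holds 4 arrays (controls 1 and 2, IPF 1 and 2) with medians from 4.27 to 4.31, and the second holds 5 (controls 3, 4 and 5, IPF 3 and 4) with medians from 4.00 to 4.05. Both sets contain both groups, so every comparison was also fitted with the array set as a block and within each set. In the second set, 12708 genes (69.1%) had the same value on 2 or more arrays and 1118 on all 5, against 253 genes (1.38%) with a shared value in the first set. A gene with the same value on all 5 arrays carries no information from that set. IPF 3 and IPF 4 were the closest pair of arrays (r = 0.992 across probe sets, 446 probe sets over 2-fold apart), where other pairs of a set had r up to 0.987 and at least 581 such probe sets. They were counted as 2 samples because the labels give each line a different patient, and the differing probe sets do not show that they are independent.

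Differences are IPF minus control on the log2 scale, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 and adjusted over all genes by the Benjamini-Hochberg method at 0.05. The fit to disease state alone over all 9 arrays, the gene lists, the rule for named genes and the alternatives of filtering, normalization, centring, variance model, array weights, probe choice, testing every probe set, the most variable genes, minimum fold, set test and leaving out each line were fixed before the data were examined. The array-set fits, the exact permutations of list scores, the merging of IPF 3 with IPF 4 and the omission of genes with 1 value on the second set were added after seeing the data.

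The 39 gene lists cover the matrix, contractile genes, signalling pathways, cell cycle, metabolism, stress, inflammation, progenitor identity and markers of other cell types. Of the 1435 distinct genes on the lists, 1306 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists. Camera with an estimated correlation, fry, and exact two-sided permutation of the list's mean score (126 splits of the 9 arrays, 60 within array sets) stand beside it. The smallest p that the splits can give is 0.00794 over all arrays and 0.0167 within sets. A list's score in a sample is the mean over its members of the log2 level minus the gene's mean. Separation of the groups over all genes was the mean correlation within groups minus that between groups, with an exact permutation test over 126 splits.

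Genes were named by this rule. ABCG2 is always named, because published isolation of these cells used it. Per direction, up to 10 genes with the largest difference past the adjusted threshold are named, filled with genes at unadjusted p under 0.01 and at least 1.5-fold, which are described as not past the adjusted threshold. Per list, up to 4 members with the smallest unadjusted p are named, and members of marker lists for other cell types may be named by value. Symbols of non-coding, open-reading-frame, olfactory and pseudogene types were not named. Genes named outside the rule are stated to have been chosen after their values were seen.

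The fits were tested on simulated data that kept the real 18394 genes' array-set means and residual spread, with independent genes. The fit to disease state recovered 9 of 67 genes changed 1.5-fold, 32 of 67 changed 2-fold and 61 of 66 changed 4-fold. With the array set as a block it recovered 29, 54 and 66 of them. Among unchanged genes 1 and 7 were called by the respective fits. A simulated shift of 0.40 in 1 of the 39 lists was recovered as 0.40 with 1 list called. Because the simulated genes were independent, this cannot show how list calls behave with correlated genes. The correlation that camera estimated in the real data was 0.842 for mitosis and 0.114 for contractile genes. An alternative that left out controls 4 and 5 together was run and set aside, because those lines had been picked by the cell cycle scores it was meant to test. Figures were drawn with matplotlib 3.10.9.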

Results

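Gene expression was measured in lung mesenchymal progenitor cells, fibroblast-like cells expanded from explanted lung, from 5 control patients and 4 patients with idiopathic pulmonary fibrosis (IPF), a scarring disease of the lung. Each cell line came from a different patient and was measured on 1 array, so n is 5 control and 4 IPF lines unless stated. Replicate spread is spread between patients, and SDs over all arrays also hold differences between the 2 array sets given below. Deposited log2 values covered 33297 probe sets, of which 18394 genes were tested. The arrays formed 2 sets, with a median value of 4.27 to 4.31 in the first (2 control and 2 IPF lines) and 4.00 to 4.05 in the second (3 control and 2 IPF lines). Camera's adjusted p with the array set as a block is given for every list, singly or as a range over several lists. Blocked medians are given for lists that passed. Values within each set are given beside lists that passed and named genes whose direction differed between the sets. Differences below are IPF minus control on the log2 scale.

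The design asks how progenitor cells from fibrotic lung differ from those of control lung. Over all 9 arrays, genes of the contractile apparatus, matrix glycoproteins, collagens and mitochondrial oxidative phosphorylation were higher in IPF lines as groups. Genes of S phase, mitosis, replication-dependent histones, cytokines, alveolar fibroblasts and mesothelium were lower. These 10 of 39 lists passed limma's camera with the preset correlation, 4 higher and 6 lower. Other splits of the 9 lines passed a median of 8 lists, and 32 of 100 drawn splits passed as many as the real grouping. Within the first array set the S phase, mitosis, histone and mesothelial lists had medians above 0 instead. With an estimated correlation 0 of the 39 lists passed (smallest adjusted p = 0.191 with an estimated correlation), and 0 passed by fry or by exact permutation. A fit with the array set as a block passed 9 lists, 8 of them the same lists, and with the block and an estimated correlation, or by exact permutation within sets, 0 passed.

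No single gene passed the adjusted threshold. Limma found 0 of 18394 genes at an adjusted p under 0.05 (smallest adjusted p = 0.999975). At an unadjusted p under 0.05 it found 87 higher and 39 lower genes, where 5% of the genes tested is 920. Other splits of the 9 lines gave a median of 353, but they do not all spread the groups over both array sets. With the array set as a block the counts were 0 and 497, and the 60 splits within sets gave a median of 670 unadjusted. The counts were 0 and 546 within the first set and 0 and 420 within the second. Array set itself, with disease state in the fit, separated 8326 genes at the adjusted threshold. Disease state was not a main axis of the data. Lines of one group were no more alike than lines of different groups, with a mean correlation of -0.196 within and -0.0632 between groups (difference -0.133, exact permutation p = 0.270 over all splits of the 9 lines). Centred within array sets, the difference was 0.0379 (exact permutation p = 0.483 over 60 splits). Across genes, which are not independent replicates, the IPF minus control differences of the 2 array sets had a Pearson correlation of -0.0715 and a Spearman correlation of -0.0414 (permutation p = 0.700 over 60 splits).

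**Figure D1:**
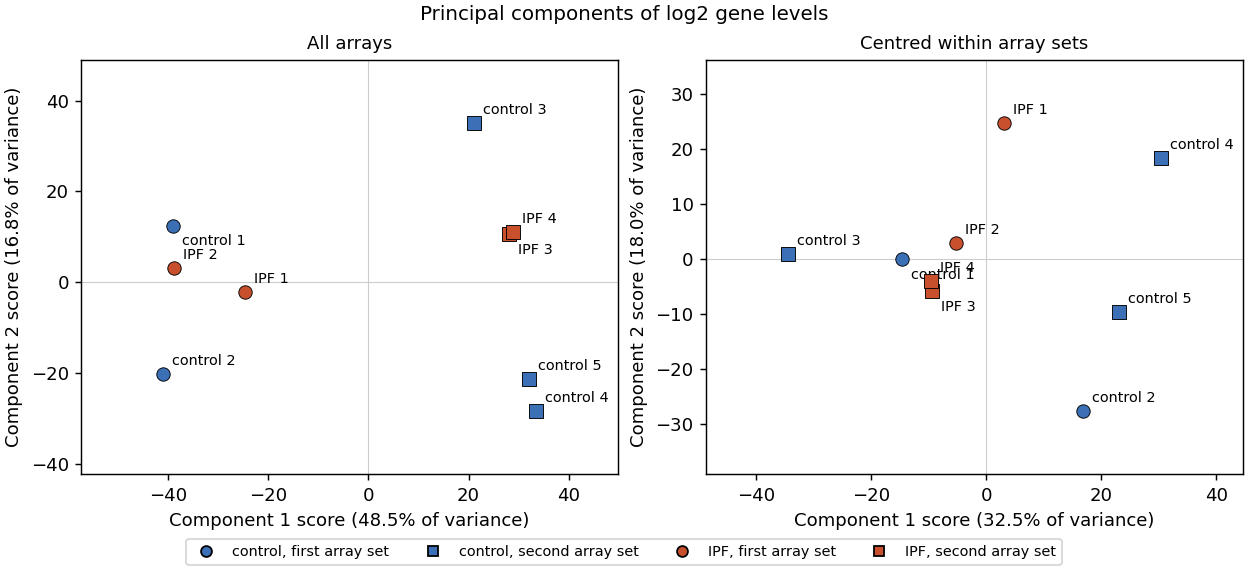
Scores of the 9 lines on the first and second principal components of log2 gene levels, over all arrays (left) and after centring each gene within its array set (right). Colour marks disease state and shape the array set. Component 1 holds 48.5% of the variance over all arrays and parts the array sets. Within sets the first component holds 32.5%, with the IPF lines from -9.65 to 3.10 and control lines on both sides of them.

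ABCG2, the efflux transporter by which these progenitors have been isolated, had a mean level of 3.11 ± 0.84 (SD) in control and 2.95 ± 0.48 in IPF lines. The difference of -0.16 (SE 0.42) was within the spread between lines, and limma's adjusted p was 0.999975. Its level was the same value, 2.53, on all 5 arrays of the second set, below the 25th percentile of each (2.66 to 2.70). Only the first set, where the difference was -0.60, therefore carries information on it. In that set it was at 4.39 and 3.54 in controls 1 and 2 and at 3.33 and 3.40 in IPF 1 and 2. All but control 1 were below the median of their array (4.27 to 4.31), so the levels are low. With control 1 left out it was 0.16 over all arrays and -0.17 within the first set. Of the 31 measured ABC transporters 13 had a higher IPF mean, and the list's median was -0.06 (camera adjusted p = 0.183, and 0.487 with the block). Its lowest member was ABCA8, a lipid transporter, at -1.47 (SE 0.56), with -1.40 and -1.75 within the first and second set. Other members named by the rule were ABCC4 at -0.50 (-1.37 and 0.08 within the sets), ABCB10 at 0.20 and ABCA2 at 0.16.

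The genes with the largest differences at an unadjusted p under 0.01, none of them past the adjusted threshold, were 4 higher and 2 lower. CORIN, a serine protease that activates natriuretic peptides, was at 3.67 ± 0.63 in control and 5.31 ± 0.88 in IPF lines, a difference of 1.64 (SE 0.44), with 0.90 and 2.24 within the array sets. NEO1, the netrin and RGM receptor neogenin, differed by 1.04 (SE 0.29), with 1.29 and 0.96 within the sets. LMOD1, the actin nucleator of smooth muscle, differed by 1.03 (SE 0.22), with 0.45 and 1.47 within the sets. PAPSS2, which makes the sulphate donor for proteoglycans, differed by 0.69 (SE 0.18), with 0.81 and 0.60 within the sets. The lower genes were BNC1, a mesothelial zinc finger protein, at -0.81 (SE 0.23) and ANXA3, a calcium-dependent phospholipid-binding protein, at -0.76 (SE 0.23). Both were lower within each set, BNC1 at -1.04 and -0.59 and ANXA3 at -1.01 and -0.60. Limma's adjusted p was 0.999975 for each of these genes.

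Contractile and smooth muscle genes were higher in IPF lines, with 28 of the 32 measured members at a higher IPF mean. The median difference was 0.27 and the mean 0.37. ACTA2, the smooth muscle actin of myofibroblasts, was at 10.05 ± 0.70 in control and 11.44 ± 0.80 in IPF lines, a difference of 1.39 (SE 0.44). TAGLN, the actin-bundling protein transgelin, differed by 0.66 (SE 0.21) and TPM1, a tropomyosin, by 0.62 (SE 0.20). The list passed limma's camera (adjusted p = 1.12e-12), but not with an estimated correlation (adjusted p = 0.191 with an estimated correlation), and its mean score gave an exact permutation p of 0.0635. Over all genes 0 members passed, while adjusted over the list alone 1 did, LMOD1 (limma adjusted p = 0.0283). At an unadjusted p under 0.05, 9 members were higher and 0 lower. Blocking on the array set, the median was 0.28 (camera adjusted p = 3.43e-11, but adjusted p = 0.501 with an estimated correlation), and 3 members passed adjusted over the list alone. They were LMOD1, TPM1 and TNS1, the focal adhesion protein tensin 1, which was named after its values were seen. Exact permutation of the blocked score over 60 splits gave p = 0.05, or 0.95 adjusted over the 39 lists. The list mean was 0.15 within the first set and 0.58 within the second, and the call was lost within the first set (adjusted p = 0.0520 by camera), while it was kept in each of the 9 fits that left out 1 line, with and without the block (unblocked medians from 0.23 to 0.39). Scores centred within sets were 0.33 and 0.37 in IPF 3 and IPF 4, the closest pair of arrays. They were 0.01 and 0.14 in IPF 1 and IPF 2 and from -0.41 to 0.12 in controls.

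**Figure D2:**
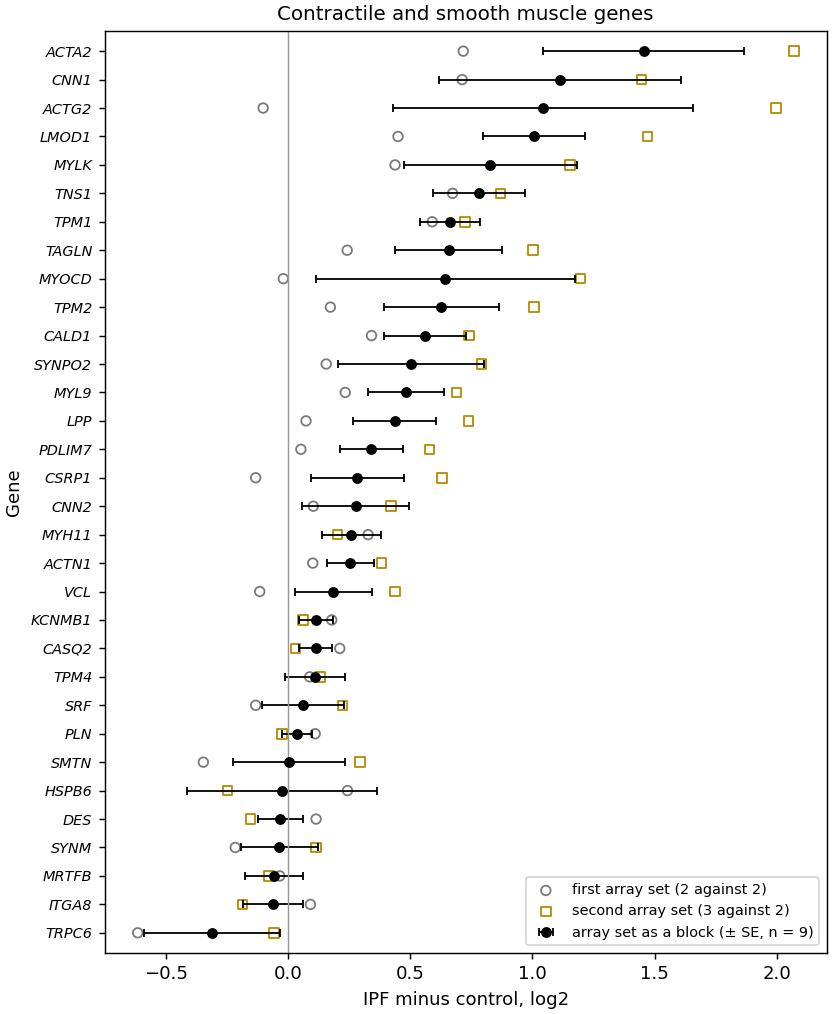
IPF minus control differences on the log2 scale for the 32 measured contractile and smooth muscle genes. Filled points with bars are estimates with the array set as a block ± SE over 9 lines, open circles and squares are the differences within the first and second array set; ACTA2 differed by 1.45 with the block, 0.72 in the first set and 2.07 in the second.

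Genes of the extracellular matrix were also higher in IPF lines. Of 54 measured glycoproteins and proteoglycans 38 had a higher IPF mean, with a median of 0.21, and of 37 collagens and collagen-processing enzymes 31 did, with a median of 0.10. HAS2, a hyaluronan synthase, differed by 1.47 (SE 0.64), SPON2, a secreted adhesion protein, by 0.85 (SE 0.37), CTHRC1, a secreted marker of fibrotic fibroblasts, by 0.65 (SE 0.25) and the basement membrane proteoglycan HSPG2 by 0.44 (SE 0.19). COL1A1, the main chain of type I collagen, differed by 0.58 (SE 0.34), with 1.36 in the first set and 0.06 in the second. The crosslinking enzyme LOX differed by 0.58 (SE 0.42) and the prolyl hydroxylases P4HA1 by 0.35 (SE 0.22) and P4HA3 by -0.68 (SE 0.34). The P4HA3 difference was -1.50 in the first set and -0.01 in the second, where controls 3 and 4 and IPF 3 and 4 had the same value, 5.50. The glycoprotein list passed camera (adjusted p = 0.00725) but had adjusted p = 0.508 with an estimated correlation. The collagen list passed camera (adjusted p = 0.0225) but had adjusted p = 0.571 with an estimated correlation. In both lists 0 members passed over all genes or adjusted over the list alone, and 4 glycoproteins and 0 collagen genes were higher at an unadjusted p under 0.05. Medians with the array set as a block were 0.20 and 0.14 (camera adjusted p = 0.0321 and 0.0153, but adjusted p = 0.912 for both with an estimated correlation), and the list means were 0.40 and 0.13 for glycoproteins and 0.24 and 0.12 for collagens within the first and second set. Without the block, leaving out control 1, control 2, control 4 or IPF 4 ended both calls, and leaving out IPF 3 ended that of the collagens, with medians from 0.07 to 0.29 for glycoproteins and from 0.08 to 0.18 for collagens. In blocked fits leaving out control 2, control 4 or IPF 1 ended both, control 1 that of the collagens and IPF 4 that of the glycoproteins. Genes of fibroblasts in fibrotic lung had a median of 0.09 over 27 members (camera adjusted p = 0.0648, and 0.102 with the block), with a mean of 0.76 within the first set and -0.10 within the second. Among its members SULF1, which trims heparan sulphate, differed by 1.35 (SE 0.74), with 2.69 and 0.44 within the sets. Matrix proteases and their inhibitors had a median of 0.02 and a mean of -0.01 over 37 members (camera adjusted p = 0.998, and 0.993 with the block), with PLAT, tissue plasminogen activator, at -1.22 (SE 0.64).

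Cytokine and chemokine genes were lower in IPF lines, with 15 of 61 measured members at a higher IPF mean and a median of -0.12. Complement C3 differed by -1.50 (SE 0.58), prostaglandin synthase PTGS2 by -1.09 (SE 0.57), interleukin IL1B by -0.94 (SE 0.43) and its receptor IL1R1 by -0.89 (SE 0.48). The list passed limma's camera (adjusted p = 1.38e-05) but had adjusted p = 0.282 with an estimated correlation, and its score gave an exact permutation p of 0.0794. Markers of alveolar fibroblasts and lipofibroblasts were lower too, with 4 of 23 members at a higher IPF mean and a median of -0.15. TCF21, a transcription factor of lung lipofibroblasts, differed by -0.71 (SE 0.64), the receptor FGFR4 by -0.75 (SE 0.53), the sodium channel SCN7A by -0.41 (SE 0.22) and the carboxylesterase CES1 by -0.31 (SE 0.24). This list passed camera (adjusted p = 0.000760) but had adjusted p = 0.236 with an estimated correlation. In both lists 0 members passed over all genes or adjusted over the list alone. Blocked on the array set, the medians were -0.15 for cytokines (camera adjusted p = 0.00139) and -0.13 for alveolar markers (camera adjusted p = 0.00585). With an estimated correlation the blocked adjusted p was 0.697 and 0.501. The means within the first and second set were -0.16 and -0.32 for cytokines and -0.36 and -0.14 for alveolar markers, and both calls were kept in each of the 9 unblocked fits that left out 1 line, with medians from -0.21 to -0.06 and from -0.18 to -0.06. In blocked fits the cytokine call was kept in all 9, and the alveolar call was lost without control 2 (camera adjusted p = 0.0664). Within the first set alone neither list passed, and within the second only the cytokines did.

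Cell cycle genes were lower in IPF lines over all arrays, by a median of -0.44 for 62 mitosis genes, -0.31 for 48 S phase and DNA replication genes and -0.24 for 47 replication-dependent histones. The number of members with a higher IPF mean was 0, 1 and 6, respectively. The mitotic kinases AURKA and AURKB differed by -1.05 (SE 0.52) and -0.48 (SE 0.31; 0.05 and -0.92 within the sets), the spindle gene CDCA8 by -0.73 (SE 0.42), the repair nuclease EXO1 by -0.73 (SE 0.48) and the histone H2BC9 by -1.09 (SE 0.56). H3C10 differed by -0.39 (SE 0.13), with -0.45 and -0.35 within the sets. All 3 lists passed limma's camera (adjusted p = 1.12e-12 for mitosis and for S phase, 1.52e-09 for histones). They had adjusted p = 0.701 (mitosis) and adjusted p = 0.571 (S phase and histones) with an estimated correlation, and exact permutation p of 0.508, 0.476 and 0.5. With the array set as a block the medians were -0.33, -0.24 and -0.26 (camera adjusted p = 1.90e-05, 2.56e-06 and 2.61e-05). With an estimated correlation the blocked adjusted p was 0.997, 0.912 and 0.912, and exact permutation p within sets was 0.617, 0.517 and 0.567. The direction differed between the sets, with means of 0.17, 0.10 and 0.10 within the first set and -0.78, -0.58 and -0.69 within the second. Scores were highest in 2 control lines of the second set, at 1.94 for mitosis in control 4 and 1.10 in control 5, against -0.73, -0.41 and -0.95 in controls 1, 2 and 3 and -0.41 to 0.03 in the 4 IPF lines. Without control 4 all 3 calls were lost, with and without the block, and the medians were 0.02, -0.05 and -0.06, against -0.74, -0.44 and -0.44 at the lowest with another line left out unblocked.

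Mesothelial markers were lower, with 7 of 18 members at a higher IPF mean and a median of -0.06 (camera adjusted p = 0.0312, but adjusted p = 0.543 with an estimated correlation). BNC1 led this list, followed in size by KRT19, a keratin, at -0.71 (SE 0.52). The list did not pass with the array set as a block (median -0.02, camera adjusted p = 0.113), and the means were 0.06 and -0.26 within the first and second set. Oxidative phosphorylation genes were higher, with 49 of 56 members at a higher IPF mean and a median of 0.09 (camera adjusted p = 0.0486, but adjusted p = 0.928 with an estimated correlation). Its complex I subunits NDUFV1 and NDUFS1 differed by 0.18 (SE 0.13) and 0.15 (SE 0.09), and the complex III subunits UQCRC1 and UQCRB by 0.24 (SE 0.15) and -0.32 (SE 0.17). This list also did not pass with the array set as a block (median 0.05, camera adjusted p = 0.0511), and the means were 0.02 and 0.07 within the sets. In unblocked fits leaving out control 3, control 4 or IPF 1 ended both calls, leaving out IPF 3 or IPF 4 also ended that of the mesothelial markers, and leaving out IPF 2 that of oxidative phosphorylation. Medians in these fits ran from -0.14 to 0.01 for mesothelial markers, turning sign, and from 0.00 to 0.16 for oxidative phosphorylation. In both lists 0 members passed over all genes or adjusted over the list alone. Genes of hypoxia and glycolysis had a median of 0.04 over 40 members (camera adjusted p = 0.600) and passed only with the block, at a median of 0.06 (camera adjusted p = 0.0487, but adjusted p = 0.912 with an estimated correlation). That call was lost without any of controls 1 to 4, IPF 1 or IPF 4.

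**Figure D3:**
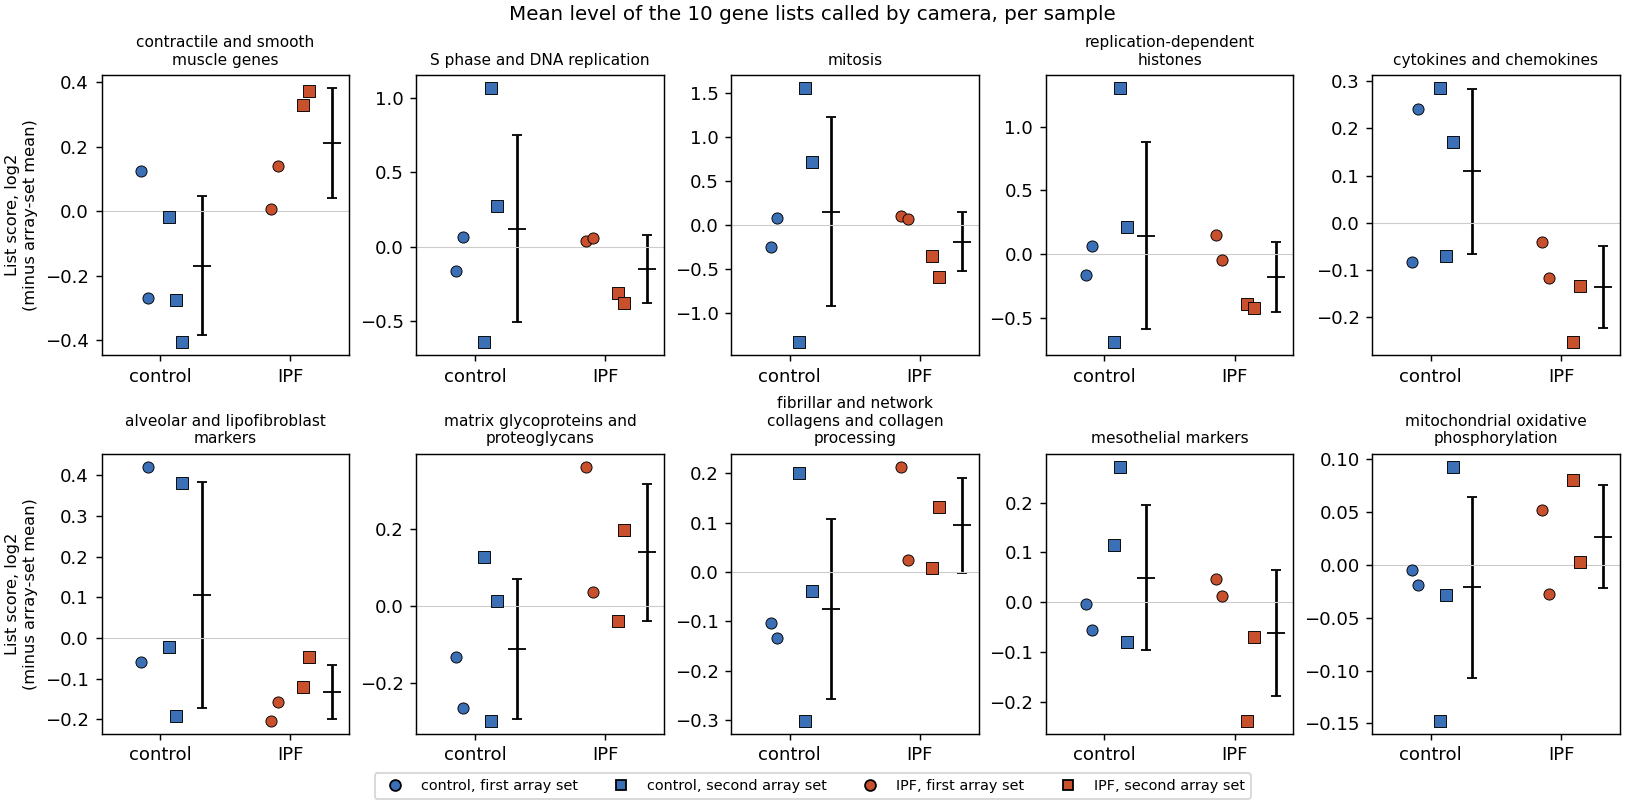
Scores of the 10 gene lists that passed camera, in each of the 9 lines, as the mean log2 level of a list's members minus the mean of the line's array set; bars are mean ± SD over 5 control and 4 IPF lines. In the second set both IPF lines lie above all controls for contractile genes (0.33 and 0.37), and control 4 has the highest mitosis score (1.55).

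Signalling lists did not pass. The median was 0.02 for the TGF-beta pathway and its targets (35 members, camera adjusted p = 0.670), where TGIF1, a repressor of SMAD-driven transcription, differed by -0.83 (SE 0.26), the co-receptor TGFBR3 by -0.79 (SE 0.43) and the ligand TGFB2 by 0.95 (SE 0.58; 0.08 and 1.63 within the sets). The Wnt list had a median of 0.03 (62 members, camera adjusted p = 0.853), with the secreted Wnt inhibitors DKK1 at -0.71 (SE 0.25) and DKK2 at -0.30 (SE 0.12) and the ligand WNT5A at 0.67 (SE 0.37; -0.14 and 1.36 within the sets). The BMP list had a median of -0.01 (32 members), with BMP6 at -0.68 (SE 0.33) and the inhibitor FSTL3 at 0.57 (SE 0.27). The Notch list had a median of 0.03 (29 members), with the receptors NOTCH2 at 0.38 (SE 0.18) and NOTCH3 at 0.41 (SE 0.22), and the Hedgehog list one of -0.03 (18 members), with GLI2 at 0.19 (SE 0.15). Mesenchymal growth factors and receptors had a median of 0.02 (47 members), with PDGFRB at 0.58 (SE 0.37) and the ligand EREG at -0.97 (SE 0.68). The TGF-beta, BMP, Hedgehog and growth factor lists had a median, a mean or a camera direction of opposite signs. None of these 6 lists passed with the block either (camera adjusted p between 0.910 and 0.993). The Hedgehog median turned to 0.03 with the block.

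Lists of progenitor identity did not pass either. Stromal surface markers had a median of 0.11 over 25 members (camera adjusted p = 0.0711), with the adhesion molecules ALCAM at 0.37 (SE 0.19; -0.05 and 0.70 within the sets) and ITGA5 at 0.36 (SE 0.20). Mesenchymal transcription factors had a median of 0.02 over 57 members, with FOXP2 at -0.33 (SE 0.11), and HOX genes one of 0.02 over 30 members, with PBX3 at 0.29 (SE 0.18), and in both the mean or the camera direction went against the median. Adipogenic genes had a median of 0.00 over 27 members, with the fatty acid transporter CD36 at 1.35 (SE 0.75), and cartilage and bone genes one of 0.05 over 29 members, with ACAN, the cartilage proteoglycan aggrecan, at 0.73 (SE 0.49). Pericyte markers had a median of -0.03 over 21 members, and adventitial fibroblast markers one of -0.02 over 22 members, with SERPINF1 at -0.83 (SE 0.63), and for the adipogenic, pericyte and adventitial lists the mean went against the median. Camera's adjusted p for these lists other than the surface markers was between 0.646 and 0.998, and with the block it was between 0.0531 and 0.955 for all 7. The medians of the transcription factors and HOX genes turned to -0.03 and -0.01 with the block.

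Markers of other cell types had median differences near 0, at 0.01 for 29 epithelial, 0.03 for 27 endothelial, 0.03 for 35 macrophage and leukocyte and 0.03 for 18 neural crest and glial markers (camera adjusted p between 0.600 and 0.670, and between 0.910 and 0.956 with the block). CLDN3 and LAMP3, of epithelium, were at 0.16 (SE 0.14) and 0.23 (SE 0.13), TEK and LYVE1, of endothelium, at 0.40 (SE 0.24) and 0.17 (SE 0.12), and CD68 and CSF1R, of macrophages, at 0.35 (SE 0.19) and 0.21 (SE 0.17). The direction differed between the sets for TEK (-0.07 and 0.69), LYVE1 (0.35 and -0.02) and CSF1R (0.46 and -0.06). The neurofilament genes NEFM and NEFL were at 2.26 (SE 0.75) and 0.43 (SE 0.17), with NEFM at 3.21 and 1.36 within the sets, and limma's adjusted p was 0.999975 for both.

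Stress, immune and housekeeping lists did not pass. Interferon-stimulated genes had a median of 0.07 over 50 members (camera adjusted p = 0.138), with IFIT3 at 0.44 (SE 0.29; 1.14 and -0.14 within the sets), and p53 targets and senescence genes one of 0.06 over 34 members (camera adjusted p = 0.117), with TP53I3 at 0.34 (SE 0.17). Antigen presentation genes had a median of -0.05 over 14 members, antioxidant and NRF2 targets one of -0.04 over 37, and immediate-early and heat shock genes one of -0.02 over 35. The glutathione synthesis genes GCLM and GCLC were at -0.65 (SE 0.32) and 0.50 (SE 0.31). The unfolded protein response list had a median of 0.00 over 34 members, cholesterol and fatty acid synthesis one of 0.06 over 31, with HMGCS1 at 0.47 (SE 0.24), and ribosomal protein genes one of 0.06 over 52. For the unfolded protein response the camera direction went against the median. Camera's adjusted p for these last 6 lists was between 0.608 and 0.972, and with the block it was between 0.0618 and 0.993 for all 8.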

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

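The tests of explanations and the counts over other splits were chosen after the results were seen, and the criterion on lines far from their group was set before. Of 222 groups of values, 11 had 1 line further from the rest than Dixon's critical value, and chance gives about 11, or 1 in 20. A group pools lines of both array sets, and the critical value allows neither for the sets nor for tied values. For P4HA3, controls 3 and 4 and IPF 3 and 4 had the same value. The values below are the line's gap to its nearest neighbour over the group's range.

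IPF 1 stood apart for 3 results. PTGS2 was at 3.26 against 5.54 to 5.91 in the other IPF lines (0.861), P4HA3 at 4.24 against 5.34 to 5.50 (0.875), and its score of adventitial fibroblast markers was 0.47 against -0.17 to -0.09 (0.862). IPF 2 stood apart for TCF21, at 8.15 against 7.58 to 7.60 (0.974), and for the unfolded protein response score, at -0.26 against 0.07 to 0.13 (0.852). IPF 3 had RPS23 at 6.91 against 7.64 to 7.75 (0.866), and IPF 4 had CORIN at 6.61 against 4.67 to 4.99 (0.835). Control 2 had P4HA3 at 6.75 against 5.50 to 5.83 (0.736) and KRT19 at 4.76 against 6.83 to 7.57 (0.736). Control 4 had PLAT at 8.30 against 10.84 to 11.69 (0.749), and control 5 had an antigen presentation score of 0.37 against -0.12 to 0.01 (0.729).

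No gene passed the adjusted threshold in the real grouping, so the count over splits decides nothing for it, since 100 of 100 drawn splits of the 9 arrays and 60 of 60 within array sets must give at least 0 (highest of the others 8574 and 0). Chance was not excluded for the other counts. The 87 higher and 39 lower genes at an unadjusted p under 0.05 were equalled or exceeded in 94 of 100 splits, and the 497 with the array set as a block in 47 of 60 (highest of the others 9885 and 2018). The splits with 8574 and 9885 genes are the same one, the split into the 2 array sets, and point to a structure of the samples. The 10 lists that passed camera were equalled in 32 of 100 splits, and the 9 with the block in 22 of 60 (highest of the others 19 and 17).

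Contractile genes were higher in IPF lines, though the list did not pass camera with an estimated correlation (adjusted p = 0.191, and 0.501 with the block). Unequal shares of the 2 array sets in the groups are argued against, since the list's mean difference was 0.38 (SE 0.14) with the array set as a block, against 0.37 without it. Slower cycling of the IPF lines stays open: with the mitosis score beside array set in the fit the difference was 0.33 (SE 0.12). The fitted slope depends largely on controls 3 and 4, with extreme mitosis scores of -1.33 and 1.55 within their set, so this fit cannot decide. The relation of the contractile and mitosis scores, centred within array sets over 9 lines, did not pass (r = -0.605, exact permutation p = 0.221, rho = -0.683, exact permutation p = 0.164, adjusted over 2 relations 0.221 and 0.164), with r = -0.897 when the 2 lines farthest from the median mitosis score were left out. Smooth muscle cells among the IPF lines may contribute and stay open, as 13 members restricted to differentiated smooth muscle had a median of 0.19 against 0.36 for the other 19 (0.11 and 0.34 with the array set as a block), within their interquartile range of 0.49, and a myofibroblast-like state of the IPF lines stays open as well.

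Cell cycle genes were lower in IPF lines over all arrays. A candidate explanation is 1 fast-cycling control line: the highest median of the mitosis list among the 9 fits that left out 1 line was 0.0204, without control 4, where the call was lost. Control 5 had the next highest mitosis score, 1.10, and without it the blocked median was -0.20 with the call kept, so the pattern may rest on both lines. Unequal shares of the array sets stay open: the blocked median was -0.33, but the blocked difference in score of -0.35 (SE 0.62) lies within its spread and the direction turned within the first set. A difference between the groups stays open, since exact permutation did not pass and a p that misses the threshold does not show that the groups cycle alike.

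The arrays split into a set of 4 and a set of 5. Separate normalization of the sets could account for it. The sets were defined by shared exact values, so the 0 values shared between them cannot test this. Disease state is argued against, since 8326 genes passed for array set with disease state in the fit and both sets hold both groups. The many tied values of the second set may come from median polish over an odd number of arrays: simulated median polish left a shared value in 95.4% of probe sets for 5 arrays of 25 probes, 88.95% for 26, 79.35% for 20 and 1.05% for 4, and in 0% for 4 arrays at each number, so the share depends on the number of probes, against 69.1% of genes observed. A difference in hybridization between the sets cannot be separated from their normalization with these values and was not tested.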

How the results depend on the processing

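The array-set, merged-line, tied-gene and permutation settings were chosen after seeing the data, the others before. In every alternative run, 0 genes passed limma's adjusted threshold (smallest adjusted p = 0.0526, with array weights). The array weights were 5.32 and 9.03 for IPF 3 and IPF 4, 1.23 to 1.38 for controls 3 to 5 and 0.27 to 0.36 in the first set. The weighted fit thus rests mainly on the second set and on the closest pair of arrays. The 87 higher and 39 lower genes at an unadjusted p under 0.05 became 76 with genes above the median level and 21 with a minimum of 1.2-fold (fewer genes tested, a stricter null), 352 over every probe set (more tested), 1113 with array weights, 497 with the array set as a block, 546 within the first set, 420 within the second, and 116 to 269 when each line was left out, with 269 without control 1 and 262 without control 3. The 10 lists past camera became 0 with an estimated correlation, 0 by fry, 0 by exact permutation over all arrays or within sets, 5 within the first set, and 3 to 15 when each line was left out, with 3 without control 4. The permutation counts decide little, since 1 list alone could not pass after adjustment over the 39 lists. Within the first set medians turned to 0.0944 for S phase, 0.140 for mitosis, 0.106 for histones and 0.0542 for mesothelial markers, of which only mitosis passed as higher. When each line was left out, the ribosomal protein list ran from -0.0785 to 0.156 and passed in the opposite direction without control 3 (-0.0785) and without IPF 1 (-0.0731), and the unfolded protein response list ran from -0.0271 to 0.0328 and passed as higher without IPF 2 (0.0328). With IPF 3 and IPF 4 merged into 1 sample, 99 genes had an unadjusted p under 0.05 by limma and 7 lists passed camera. Except for the numbers of genes tested, the cause of these changes was not tested. Separation of the groups and ABCG2 passed under no setting run. No paired analysis was possible because no number in the labels ties lines of the 2 groups together. Signal over background was not analysed here, so what it limits was not tested.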

Other observations

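Some list members outside the naming rule differed by over 1 on the log2 scale, in the same direction within both array sets, and were chosen after their values were seen, and none passed limma's adjusted threshold (adjusted p = 0.999975 for each). Among matrix genes the small proteoglycan BGN was at 1.29 (SE 0.61) and the integrin ligand EDIL3 at 1.39 (SE 0.84). Among lower ones the endothelin receptor EDNRB was at -1.83 (SE 1.5), the lung mesenchyme transcription factor TBX4 at -1.15 (SE 0.83) and the alarmin IL33 at -1.12 (SE 0.63). Outside the lists, the retinaldehyde dehydrogenase ALDH1A1 was at 1.93 (SE 0.65), with 0.30 in the first array set and 3.32 in the second. RTN1, a reticulon of the endoplasmic reticulum, was at 1.47 (SE 0.50), with 1.54 and 1.49 within the sets.

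The tests of the hypotheses below were chosen after the results were seen. Cell cycle activity may be the largest axis on which lines of an array set differ. The first component of genes centred within array sets, which holds 32.5% of the variance, correlated with the mitosis score over the 9 lines at r = 0.929 (exact permutation within sets p = 0.00174, rho = 0.933, exact permutation p = 0.00174, both 0.00347 adjusted over 2 relations). Without the 2 lines farthest from the median of the component r was 0.840. The sets hold 4 and 5 lines, too few for a correlation within each. The 62 mitosis genes are among the 18394 that form the component, so the values are not fully independent.

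Control lines may be more varied than IPF lines. Within array sets the median over genes of the log2 ratio of control to IPF SD was 0.56, with a median SD of 0.16 in control and 0.11 in IPF lines. Of the 60 splits within array sets 2 gave a ratio as large (exact two-sided permutation p = 0.0333), and when each line was left out the ratio ran from 0.39, without IPF 3, to 1.37. IPF 3 and IPF 4 are the closest pair of arrays, so part of the ratio rests on that pair. The hypothesis was found and tested on the same data.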
